A study of Arabidopsis thaliana with 75 samples.

How the data were processed

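The series compares Arabidopsis plants of Col-0, of the mta line (MTA is the methyltransferase subunit of the m6A writer) and of 35SALKBH10B (a line that overexpresses the m6A demethylase ALKBH10B). Seedlings were 14 days old per the labels and were either untreated or held for 4 h in 1 µM flg22, the bacterial flagellin peptide. Leaves were 4 weeks old, and their titles give a time of 00 or 24 with no unit. The leaf titles name Pst while the treatment tag of the same samples names flg22, so the leaf groups are called only 00 and 24 here. Names of untreated seedling data give 4 h for mRNA and the start for GMUCT and m6A. The labels do not settle whether these seedlings were collected at the start or after 4 h. Changes with flg22 in GMUCT and m6A may thus include 4 h of time. The 75 samples form 25 groups of 3. Whether replicates were separate cultures is not given in the sources used here, so p-values measure the spread between samples, which may be technical. Replicate numbers were tested for shared structure by correlating residuals between groups, with pairs above 0.1 counted. In seedling mRNA 0 pairs passed 0.1, while in leaves 3 of 3 same-number pairs of Col-0 and mta at 24 did, at 0.136 to 0.297, and up to 2 of 3 between other leaf groups and in GMUCT. Samples were fitted as unpaired, with a replicate block as an alternative.

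For mRNA, the deposited files hold whole read counts per feature that the authors obtained from 2 rounds of poly(A) selection and paired-end sequencing, with featureCounts 2.0.1 named in the seedling file header. STAR and TAIR10 are named per the submitters' processing notes without versions. Of 62925 annotated features, the 32844 gene loci were analysed. Counts in seedling libraries did not separate the strands: at least 26.1% of counts per library lay in NPC features that mirror genes of the other strand, so a seedling gene with an antisense partner cannot be told apart from it. MTA itself has 0 mRNA counts, because a locus of the same strand covers it. GMUCT (genome-wide mapping of uncapped and cleaved transcripts) was deposited as RPM, which is scaled by the sum over the genes of a library. Every RPM column divides back into whole reads (100% of values within 0.01), so depth is known. The deposited log2 values of uncapped over total RNA hold 1 value per group, without replicates, and were used only to check the base of the logarithm. For m6A, the authors deposited MACS2 narrow peaks per library and strand, with a fold enrichment over the background of the caller as a ratio, and −log10 p and −log10 q per the file headers' layout. Seedling peak lists reach down to q 0.01 and leaf lists to p 0.01, so tissues are not compared. The depth of the m6A libraries is unknown.

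The comparisons use 12 seedling mRNA libraries, 12 leaf mRNA libraries, 18 GMUCT libraries and 26 m6A libraries. Another 12 seedling count columns, whose names did not map to a group without a guess, were not used, so mRNA of 35SALKBH10B (6 samples) and its uncapped share are not analysed here. Untreated Col-0 has 2 m6A peak lists (replicates 2 and 3), and m6A in mta leaves at 24 is not analysed here. The share of peaks in 3′ untranslated regions was replaced by the share of summits in the last 20% of the gene span, since exon annotation was not used here.

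Groups were compared in R 4.3.3. For mRNA, edgeR 4.0.16 fitted all libraries of a tissue together by quasi-likelihood with TMM scaling and filterByExpr, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Seedlings had 19887 genes tested and leaves 18824. CPM of named genes are scaled by the TMM factors, and CPM beside peaks by the library sum. For GMUCT, limma 3.58.1 fitted log2(RPM + 1) of the 19277 genes with an RPM of 1 or more in at least 3 libraries. This scale understates changes of genes with low RPM. RPM are shares of a library, so a few strongly risen genes lower all others. Uncapped RNA relative to mRNA was the interaction of library kind with the contrast in limma, over 17596 genes. Peaks were assigned to the gene of the opposite strand at their summit, which placed at least 99.2% of summits of each library in a gene. Peak numbers, covered length, genes with a peak and the share in the last 20% of genes were compared by exact two-sided permutation of libraries. These were adjusted within a family of 7 comparisons, and the smallest p with 3 against 3 or 3 against 2 libraries is 0.1. Genes with a peak in every untreated Col-0 library of a tissue were compared with genes without one in 20 bins of expression, as the difference of median log2 levels per library.

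A set of 17 gene lists with 303 genes was written from general knowledge: indole defence, PTI response and PTI signalling (pattern-triggered immunity), salicylic acid, jasmonate and ethylene, NLR receptors, heat and ER chaperones, photosynthesis, auxin response, cell division, circadian clock, senescence, m6A machinery, RNA decay, and markers of root, seed and guard cell lineage. Lists were tested by camera with a preset correlation of 0.01, again with an estimated correlation, and by fry. Genes are named by a rule: the 8 largest rises and 8 largest falls past the threshold with an average log2 level of 3 or more and no overlap between replicates, up to 4 members per list with the largest change, MTA and ALKBH10B always, and for peaks up to 8 genes with a peak in every library of one group and none of the other, by mean RNA. Any gene named outside the rule is called so. Folds against groups at 0 counts are lower bounds from a floor of 3 counts over the group, and cover counting error only.

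The comparisons, tests, lists, named-gene rule and most alternatives were chosen before the data were examined. The GMUCT comparisons between genotypes and their interactions, the share in the last 20% of genes, sets of 200 genes chosen in one assay or tissue and tested in another, the restriction to gene loci, and alternatives that chose m6A genes in Col-0 libraries with flg22 or at 24, or in both groups, and list tests without 35SALKBH10B replicate 3 with flg22, were chosen afterwards. Alternatives were DESeq2 1.42.0 (size factors, Wald test), other filters, a replicate block, fits of the compared groups alone, a fold of 2, pseudocounts of 0.1 and 5, quantile and TMM scaling of RPM, edgeR on recovered reads, stricter peaks, equal numbers of top peaks, and leaving out each library. Prepared tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

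Seedling mRNA libraries held 9442047 to 13222937 counts in gene loci, leaf libraries 20467621 to 44052628, and GMUCT libraries 3107893 to 41465534 reads. The steps were tested on simulated data with the depth and spread of the libraries. The edgeR step recovered 86.4% of genes changed 2-fold in seedlings and 62.1% in leaves. The limma step recovered 9.23% at 2-fold and 84.6% at 4-fold in GMUCT, and 6.25% and 75.8% for uncapped relative to mRNA, so many changes of 2-fold can be missed there where few genes change. False calls were 6.29% of those made in seedlings, 4.10% in leaves and 4.69% in GMUCT. A shift of 0.5 put into the simulated m6A genes was found as 0.52.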

Results

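The overexpression line carried far more uncapped ALKBH10B RNA than Col-0. In GMUCT, ALKBH10B, the m6A demethylase, stood at 440.3 ± 29.5 RPM in untreated 35SALKBH10B and 37.0 ± 0.872 in untreated Col-0 (mean ± SD, n = 3 each), a log2 fold change of 3.54 ± 0.20 (SE, limma adjusted p = 1.3e-08). A locus of the same strand covers 99.2% of MTA, so its reads may belong to either. Uncapped MTA RNA was lower in untreated mta, at 9.86 ± 0.189 against 21.3 ± 2.75 RPM in Col-0 (−1.03 ± 0.25, limma adjusted p = 0.03), a call lost in 5 of 14 settings (adjusted p up to 0.12). MTA did not pass between untreated 35SALKBH10B and Col-0 (0.44 ± 0.25, adjusted p = 0.27).

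In Col-0 seedlings, flg22 strongly raised enzymes of indole defence. CYP71A12, a cytochrome P450 that acts on indole acetaldoxime, rose from 106 ± 5.08 to 3643 ± 136 CPM (n = 3 each), a log2 fold change of 5.10 ± 0.07 (SE, edgeR QL adjusted p = 1.3e-37). CYP79B2, which makes that aldoxime from tryptophan, rose from 213 to 3457 CPM, and ASA1, of tryptophan synthesis, from 101 to 1368. PROPEP3, a danger-peptide precursor, rose from 23.3 to 782 CPM. Among all genes, the aminotransferase AT4G28420 rose from 2.71 ± 1.17 to 342 ± 12.4 CPM (7.003 ± 0.13), CYP82C2 by 5.64 ± 0.10 and the peroxidase PRX52 by 5.54 ± 0.09. TT4, the chalcone synthase of flavonoid synthesis, fell from 147 ± 7.83 to 13.5 ± 0.994 CPM (−3.44 ± 0.11), and NAS1, a nicotianamine synthase, from 29.8 ± 1.09 to 1.31 ± 0.683 (−4.54 ± 0.25). EM6 was at least 45.3-fold higher and PRP3 at least 30.2-fold lower with flg22, each against a group at 0 counts. By edgeR QL with BH, 11668 of 19887 tested genes passed, 5557 up and 6111 down, while 8219 did not pass. Among those that passed, 2536 rose and 2790 fell at least 2-fold, and 886 rose and 497 fell at least 4-fold. Replicates did not overlap in 10936 of the genes that passed, where 10% of genes would not overlap by chance if not chosen by the test, so part of this count follows from that choice. Counts do not separate strands, and TT4 and NAS1 have overlapping partners on the opposite strand over 78.6% and 93.9% of their length. With every annotated feature tested, 18662 passed in place of 11668, and 5326 passed with a fold of 2 or more.

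Of 18 measured indole-defence genes, 17 rose and 1 fell with flg22 in Col-0 seedlings, and 18 passed adjusted over the list alone. Their median log2 fold change was 3.04 (camera adjusted p = 4.5e-66, 5.0e-05 with an estimated correlation). IGMT2, an indole glucosinolate methyltransferase, rose from 16.2 to 358 CPM. Of 14 PTI response genes, 11 rose and 1 fell (12 over the list alone, median 2.62, camera adjusted p = 2.0e-20, estimated 6.9e-05), with NHL10 rising by 4.02 ± 0.10. Among 17 PTI signalling genes, 13 rose and 2 fell (17 over the list alone, median 0.80, camera adjusted p = 2.2e-05, estimated 0.025). The chitin receptor kinase CERK1 rose from 45.4 to 239.9 CPM, the co-receptor BAK1 from 109.8 to 422, and the NADPH oxidase RBOHD by 1.45 ± 0.07. In the jasmonate and ethylene list, 21 of 28 rose and 3 fell (24 over the list alone, median 0.79, camera adjusted p = 6.2e-06, estimated 0.041). ACS2, an ethylene synthesis enzyme, rose by 3.58 ± 0.09 and the lipoxygenase LOX4 by 1.92 ± 0.08. For salicylic acid, 12 of 22 rose and 2 fell (14 over the list alone, median 0.47, camera adjusted p = 0.013, estimated 0.041), with the regulator CBP60g up by 2.30 ± 0.08 and the transporter EDS5 by 2.12 ± 0.10.

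Photosynthesis genes fell without exception. All 30 measured members passed downward in Col-0 seedlings with flg22, and 30 did so adjusted over the list alone (median −1.13, camera adjusted p = 2.2e-24, estimated 0.041). RBCS1B, a Rubisco small subunit, fell from 457 ± 42.6 to 75.3 ± 10.6 CPM, and the antenna protein LHCB2.2 from 813 ± 27.1 to 160.1 ± 12.5. RBCS1B and LHCB2.2 overlap genes of the opposite strand over 97.8% and 63.7% of their length. The other 11 lists did not pass by camera, at adjusted p = 0.15 to 0.99. Within heat and ER chaperones, 9 of 18 rose and 8 fell (17 over the list alone, median 0.31, adjusted p = 0.23), with the ER chaperone BIP3 up by 3.17 ± 0.16 and HSP22 down (−1.98 ± 0.16). Clock genes had 9 of 13 up and 3 down (12 over the list alone, median 0.95, adjusted p = 0.31), PRR5 rising by 2.04 ± 0.18. NLR receptors had 8 of 14 up and 2 down (10 over the list alone, median 0.44, adjusted p = 0.26), RPS4 by 1.296 ± 0.14. Auxin response had 2 of 12 up and 5 down (7 over the list alone, median −0.78, adjusted p = 0.15), with GH3.3 down (−2.65 ± 0.10). Cell division had 1 of 11 up and 6 down (7 over the list alone, median −0.56, adjusted p = 0.31), and RNA decay 3 of 21 up and 6 down (9 over the list alone, median −0.13, adjusted p = 0.31), where the decapping activator DCP1 changed by −1.01 ± 0.07. Root markers had 1 of 12 up and 6 down (8 over the list alone, median −0.79, adjusted p = 0.25), guard cell markers 0 of 9 (0 over the list alone, median −0.27, adjusted p = 0.55). The only seed gene tested, EM6, rose (adjusted p = 0.34). Senescence had 3 of 7 up and 3 down (6 over the list alone, adjusted p = 0.99), with a median of 0.17, a mean of −0.35 and an upward test.

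The m6A machinery did not move as a group with flg22, though single members did. Of 19 measured members in Col-0 seedlings, 3 rose and 5 fell (8 over the list alone, camera adjusted p = 0.55), with a median of −0.18, a mean of 0.02 and a downward test. The demethylase ALKBH10B rose from 70.0 ± 2.53 to 230.4 ± 22.8 CPM (n = 3 each, 1.72 ± 0.08, edgeR QL adjusted p = 1.4e-20), and ALKBH9A from 0.401 to 7.23 CPM. The m6A reader ECT3 fell from 159 to 71.2 CPM, and ECT9 fell as well (−1.04 ± 0.14). In mta, ALKBH10B went from 133 ± 2.38 to 175 ± 4.32 CPM (0.40 ± 0.08, adjusted p = 4.6e-05), a smaller response by the interaction (−1.32 ± 0.11, adjusted p = 4.2e-12). Untreated mta already exceeded untreated Col-0 in ALKBH10B (0.92 ± 0.08, adjusted p = 6.9e-12), and in the writer subunits VIR (0.80 ± 0.10, adjusted p = 6.4e-08) and FIP37 (0.57 ± 0.15).

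Untreated mta seedlings had higher mRNA of most indole-defence and PTI response genes, which flg22 raised in Col-0. CYP71A12 rose from 106 ± 5.08 in Col-0 to 632 ± 0.899 CPM in mta (n = 3 each, 2.57 ± 0.06, edgeR QL adjusted p = 1.8e-28), CYP71A13 by 2.35 ± 0.09 and PAD3, the last enzyme of camalexin synthesis, by 1.88 ± 0.07. The beta-glucosidase BGLU27 rose from 2.60 ± 0.295 to 42.2 ± 1.14 CPM (4.02 ± 0.14), PRX52 by 3.21 ± 0.09 (adjusted p = 1.4e-26) and MRD1 by 4.34 ± 0.17, although MRD1 lies over a gene of the opposite strand for 98.8% of its length. WRKY38 fell from 15.8 ± 1.94 to 4.74 ± 1.18 CPM (−1.73 ± 0.21) and AT3G22235 from 188 ± 16.3 to 61.8 ± 2.24 (−1.60 ± 0.09). By edgeR QL with BH, 6580 of 19887 genes passed, 3593 up and 2987 down, with 914 up and 178 down at least 2-fold. Replicates did not overlap in 6348 of these (10% by chance without that choice). With every annotated feature tested, 9964 passed, and 1092 passed with a fold of 2 or more.

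In untreated mta, 16 of 18 indole-defence genes rose against Col-0 and 0 fell (16 over the list alone, median 1.04, camera adjusted p = 8.7e-50, estimated 5.2e-05). PTI response genes had 8 of 14 up and 2 down (10 over the list alone, median 0.68, camera adjusted p = 1.7e-10, estimated 0.00090), NHL10 by 1.73 ± 0.10 and WRKY30 by 1.63 ± 0.19. Chaperones of heat and the ER had 12 of 18 up and 2 down (14 over the list alone, median 0.69, camera adjusted p = 6.7e-10, estimated 0.020). HSP101, a disaggregase, rose from 21.9 ± 2.86 to 94.1 ± 2.06 CPM (2.096 ± 0.13, edgeR QL adjusted p = 7.3e-16) and HSP90.1 from 54.4 to 190.0. Photosynthesis had 1 of 30 up and 22 down (24 over the list alone, median −0.40, camera adjusted p = 1.1e-11), a call lost at adjusted p = 0.14 with an estimated correlation, and LHCB6 fell from 1149 to 612 CPM. Jasmonate and ethylene genes had 12 of 28 up and 5 down (20 over the list alone, median 0.29, camera adjusted p = 0.00013), and senescence 3 of 7 up and 0 down (3 over the list alone, median 0.30, adjusted p = 0.023). These last calls were lost, each at adjusted p = 0.092 with an estimated correlation. SAG13 rose from 119 to 291 CPM and ACS2 by 2.22 ± 0.09. The other 11 lists did not pass by camera (adjusted p = 0.082 to 0.92). Among them, salicylic acid had 10 up and 3 down (13 over the list alone, median 0.25, adjusted p = 0.082), with FMO1 up by 2.12 ± 0.25. Guard cell markers had a median of 0.33, a mean of 0.07 and a downward test.

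The flg22 response of indole-defence genes was smaller in mta than in Col-0, from a higher start to a lower end. CYP71A12 went from 632 ± 0.899 to 2830.1 ± 120.2 CPM in mta (n = 3 each, 2.16 ± 0.06), a difference in response of −2.94 ± 0.08 (interaction, edgeR QL adjusted p = 6.0e-26). IGMT2 went from 54.2 to 137 CPM in mta (interaction −3.14 ± 0.13) and PAD3 from 591 to 672, against 161 to 855 in Col-0 (interaction −2.23 ± 0.09). AT4G28420 had the largest negative interaction of the named genes (−3.92 ± 0.17). HSP17.6II, a small heat shock protein, fell in Col-0 from 52.5 to 15.9 CPM and stood at 105 and 119 in mta (interaction 1.90 ± 0.14), and WRKY38 had a positive interaction of 2.68 ± 0.31. In mta, flg22 raised CYP82C2 by 3.49 ± 0.08 and BIP3 by 2.91 ± 0.15, and lowered the ribonuclease RNS1 (−3.17 ± 0.21) and the glucosinolate enzyme CYP79F1 (−2.61 ± 0.15). By edgeR QL with BH, 8387 of 19887 genes passed in mta, 4367 up and 4020 down (1050 and 1030 at least 2-fold), with 8130 not overlapping between replicates (10% by chance without that choice). For the interaction, 3803 genes passed, 1375 positive and 2428 negative (395 and 889 at least 2-fold). With every annotated feature tested, 12990 passed in mta. With a fold of 2 or more, 2080 passed in mta and 1284 for the interaction.

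For the difference of responses, indole defence had 0 positive and 17 negative of 18 genes (17 over the list alone, median −1.52, camera adjusted p = 2.8e-78, estimated 1.4e-05). PTI response had 1 positive and 10 negative of 14 (12 over the list alone, median −1.04, camera adjusted p = 1.1e-15, estimated 0.00019), including PROPEP3 at −2.75 ± 0.13 and CYP81F2 at −1.98 ± 0.09. PTI signalling had 1 positive and 9 negative of 17 (10 over the list alone, median −0.39, camera adjusted p = 9.8e-05, estimated 0.022), with CERK1 at −1.10 ± 0.12 and BAK1 at −1.04 ± 0.10. Jasmonate and ethylene had 1 positive and 17 negative of 28 (19 over the list alone, median −0.48, camera adjusted p = 9.5e-10, estimated 0.018), including ACS2 at −2.61 ± 0.12 and the defensin PDF1.2A at −1.98 ± 0.14. Photosynthesis had 18 positive and 3 negative of 30 (24 over the list alone, median 0.40, camera adjusted p = 1.5e-13), lost at adjusted p = 0.17 with an estimated correlation. Heat and ER chaperones had 7 positive and 2 negative of 18 (13 over the list alone, median −0.02, mean 0.41, upward test, camera adjusted p = 0.0011), lost at adjusted p = 0.18 with an estimated correlation. The other 11 lists did not pass (adjusted p = 0.10 to 0.88), salicylic acid among them (4 positive, 6 negative, 11 over the list alone, median −0.11, adjusted p = 0.62), although ICS1, of salicylic acid synthesis, had −1.23 ± 0.16.

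Within mta, flg22 still raised 17 of 18 indole-defence genes and lowered 1 (18 over the list alone, median 1.33, camera adjusted p = 4.6e-40, estimated 9.4e-05). PTI response had 11 of 14 up and 0 down (12 over the list alone, median 1.32, camera adjusted p = 6.4e-19, estimated 9.4e-05), and PTI signalling 12 of 17 up and 2 down (15 over the list alone, median 0.40, camera adjusted p = 0.0019, estimated 0.049). Salicylic acid had 16 of 22 up and 0 down (16 over the list alone, median 0.63, camera adjusted p = 0.00016, estimated 0.012), CBP60g by 1.503 ± 0.08. Among heat and ER chaperones, 12 of 18 rose and 2 fell (14 over the list alone, median 0.38, camera adjusted p = 1.4e-07, estimated 0.039). Photosynthesis had 0 of 30 up and 30 down (30 over the list alone, median −0.66, camera adjusted p = 3.1e-22), with RBCS1B at −1.87 ± 0.13, a call lost at adjusted p = 0.051 with an estimated correlation. The other 11 lists did not pass (adjusted p = 0.092 to 0.89). In RNA decay the median was 0.02 and the mean 0.03 with a downward test.

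**Figure D1:**
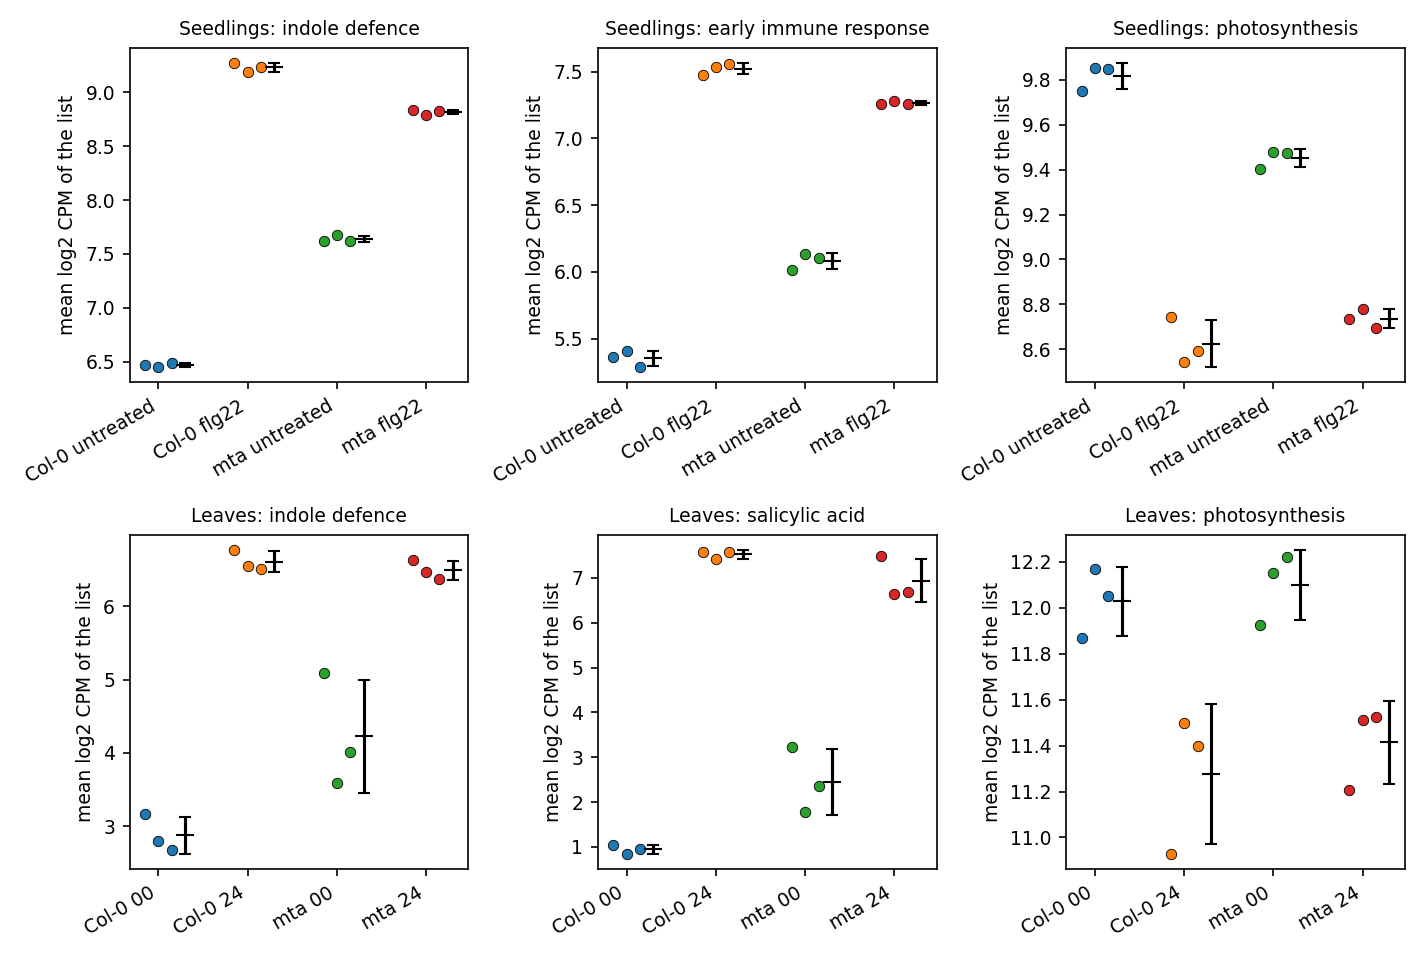
Mean log2 CPM of gene lists in each mRNA library (dots) with group mean ± SD, n = 3 per group, in seedlings (top) and leaves (bottom). Untreated mta seedlings lie above untreated Col-0 for indole defence and early immune response, and 1 library of mta leaves at 00 lies above the other 2.

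In Col-0 leaves, most jasmonate and ethylene genes and all measured salicylic acid genes rose by 24. TAT3, a tyrosine aminotransferase induced by jasmonate, rose from 0.645 ± 0.165 to 7841 ± 1178 CPM (n = 3 each, 13.55 ± 0.71, edgeR QL adjusted p = 4.0e-08), and VSP2, a jasmonate-induced storage protein, from 1.49 ± 0.537 to 3155 ± 389.8 (11.05 ± 0.57). WRKY46, of salicylic acid defence, rose from 1.68 ± 0.174 to 107 ± 8.96 CPM (5.98 ± 0.43). AT1G33950 was at least 3273-fold higher against a group at 0 counts. DREB26, a transcription factor, fell from 149.6 ± 36.4 to 0.275 ± 0.0374 CPM (−9.08 ± 0.27) and so did PHI-1, a phosphate-induced gene (−8.83 ± 0.49). By edgeR QL with BH, 12860 of 18824 genes passed, 6705 up and 6155 down, with 3909 up and 3396 down at least 2-fold, and 12585 not overlapping (10% by chance without that choice). The number was 7305 with a fold of 2 or more. No list call held with an estimated correlation (adjusted p = 0.33 to 0.74), so the list calls in these leaves rest on the preset one.

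All 22 salicylic acid genes measured in Col-0 leaves rose by 24 (22 over the list alone, median 6.43, camera adjusted p = 5.1e-18). Of 28 jasmonate and ethylene genes, 25 rose and 2 fell (27 over the list alone, median 3.66, camera adjusted p = 9.3e-09, 0.46 with an estimated correlation), JAZ10 by 8.23 ± 0.75. Indole defence had 16 up and 0 down (16 over the list alone, median 2.98, camera adjusted p = 1.0e-07). Heat and ER chaperones had 15 up and 0 down (15 over the list alone, median 3.27, camera adjusted p = 2.2e-07), and NLR receptors 12 up and 0 down (12 over the list alone, median 1.27, camera adjusted p = 1.4e-06), the helper NRG1.2 going from 2.90 to 46.3 CPM. PTI signalling had 15 up and 1 down (16 over the list alone, median 1.35, camera adjusted p = 8.8e-06, 0.35 with an estimated correlation), the chitin receptor LYM2 by 3.23 ± 0.19. Photosynthesis had 0 up and 21 down (21 over the list alone, median −0.68, camera adjusted p = 0.0014, 0.74 with an estimated correlation), with a fall of RBCS1B (−2.15 ± 0.24). The other 10 lists did not pass (adjusted p = 0.086 to 0.90), and auxin response had a median of −0.32, a mean of 0.02 and a downward test. ALKBH10B rose by 0.44 ± 0.13 (adjusted p = 0.012, lost in 2 of 15 settings, up to 0.066).

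Leaves of mta at 00 had higher mRNA of part of the defence genes than Col-0, unevenly between libraries. ANAC019, a jasmonate-responsive transcription factor, differed by 3.15 ± 0.69 (n = 3 each) and BIK1, a PTI kinase, by 1.43 ± 0.34. SHM7, a serine hydroxymethyltransferase, fell from 323 ± 25.8 to 61.8 ± 22.7 CPM (−2.39 ± 0.24) and the homeobox gene HAT1 from 71.1 ± 3.12 to 15.1 ± 3.68 (−2.23 ± 0.18). By edgeR QL with BH, 5410 of 18824 genes passed, 2912 up and 2498 down (1563 and 258 at least 2-fold), with 5143 not overlapping (10% by chance without that choice). The number was 3574 without Col-0 replicate 2 at 00 and 1821 with a fold of 2 or more. Salicylic acid had 11 of 22 up (12 over the list alone, median 1.16, camera adjusted p = 1.1e-05), jasmonate and ethylene 15 up and 1 down of 28 (19 over the list alone, median 1.58, adjusted p = 1.1e-05), indole defence 12 up (14 over the list alone, median 1.37, adjusted p = 5.1e-05). Heat and ER chaperones had 11 up (15 over the list alone, median 1.51, adjusted p = 1.8e-06) and clock genes 6 up and 1 down (7 over the list alone, median 0.49, adjusted p = 0.035). All of these list calls were lost at adjusted p = 0.63 with an estimated correlation. The other 12 lists did not pass (adjusted p = 0.051 to 0.90), although senescence moved from 0.096 to 0.041 with a replicate block. The median was −0.13 and the mean 0.13 for auxin response, and −0.06 and 0.37 for PTI signalling, each with an upward test. The mean log2 CPM of salicylic acid genes was 3.23, 1.78 and 2.35 in the mta libraries at 00, against 0.84 to 1.03 in Col-0.

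From 00 to 24, VSP2 and PR2 rose less in mta leaves than in Col-0. VSP2 rose by 7.31 ± 0.49 in mta, a difference in response of −3.74 ± 0.58 (n = 3 per group, edgeR QL adjusted p = 0.0041), and PR2, a beta-glucanase, went from 42.3 to 327 CPM in mta against 2.68 to 848 in Col-0 (interaction −5.34 ± 0.77). PHI-1 and DREB26, which fell in Col-0, had positive interactions of 4.75 ± 0.55 (adjusted p = 0.0011) and 3.91 ± 0.34. BEE3, a brassinosteroid-induced factor, fell in mta from 74.2 ± 17.1 to 0.513 ± 0.0843 CPM, and ALD1, of pipecolic acid synthesis, rose by 7.09 ± 0.68. By edgeR QL with BH, 11108 genes passed in mta, 5826 up and 5282 down (3045 and 2441 at least 2-fold), with 10711 not overlapping (10% by chance without that choice), and 5486 with a fold of 2 or more. For the interaction 1834 passed, 898 positive and 936 negative (526 and 581 at least 2-fold), and 1107 with a fold of 2 or more. The interaction count was 923 and 1168 without Col-0 replicates 2 and 3 at 00, 1075 and 841 without Col-0 replicates 1 and 3 at 24, and 883 and 809 without mta replicates 2 and 3 at 24. It was 2970 by DESeq2, 2900 with a replicate block and 3194 with replicates 2 and 3 alone.

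In mta leaves all 22 salicylic acid genes rose by 24 (22 over the list alone, median 4.48, camera adjusted p = 2.2e-19). Jasmonate and ethylene had 22 up and 1 down (23 over the list alone, median 2.48, adjusted p = 2.3e-08), NLR receptors 12 up and 1 down (13 over the list alone, median 1.26, adjusted p = 6.7e-08), indole defence 14 up and 1 down (15 over the list alone, median 1.70, adjusted p = 5.6e-06), and heat and ER chaperones 12 up and 0 down (13 over the list alone, median 1.83, adjusted p = 7.0e-06). PTI signalling had 14 up and 1 down (16 over the list alone, median 1.16, adjusted p = 3.7e-05), senescence 5 up and 0 down (5 over the list alone, median 1.36, adjusted p = 0.028), photosynthesis 0 up and 22 down (27 over the list alone, median −0.64, adjusted p = 8.8e-05) and cell division 0 up and 7 down (7 over the list alone, median −1.16, adjusted p = 0.011). With an estimated correlation these calls were lost, at adjusted p = 0.34 to 0.67. The other 8 lists did not pass (adjusted p = 0.17 to 1.00). Auxin response (median −0.27, mean 0.07) and root markers (median −0.02, mean 0.48) had downward tests. For the interaction, salicylic acid had 0 positive and 10 negative (15 over the list alone, median −1.22, camera adjusted p = 1.1e-11), jasmonate and ethylene 1 and 7 (17 over the list alone, median −1.36, adjusted p = 6.9e-08), indole defence 0 and 7 (10 over the list alone, median −1.56, adjusted p = 7.8e-08), heat and ER chaperones 0 and 9 (11 over the list alone, median −1.09, adjusted p = 3.1e-07) and PTI signalling 0 and 2 (4 over the list alone, median −0.39, adjusted p = 0.0042). With an estimated correlation adjusted p was 0.47, 0.61, 0.47, 0.47 and 0.66. The other 12 lists did not pass (adjusted p = 0.093 to 0.90), photosynthesis with a median of −0.01, a mean of 0.06 and an upward test.

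Uncapped RNA of most indole-defence and PTI response genes rose with flg22 in Col-0 seedlings, as their mRNA did. In GMUCT, CYP71A12 rose from 102 ± 29.3 to 2688 ± 129 RPM (n = 3 each, 4.75 ± 0.44, limma adjusted p = 9.7e-07), AT4G28420 from 8.62 ± 1.91 to 633 ± 58.8 (6.06 ± 0.45) and CYP82C2 by 5.35 ± 0.61. AT1G72610, a germin-like protein, fell from 216 ± 20.3 to 17.3 ± 2.12 RPM (−3.57 ± 0.29), as did the anion channel CLC-B (−3.52 ± 0.40) and TT4 (−3.31 ± 0.39). ALKBH10B rose by 1.23 ± 0.20 (adjusted p = 1.2e-04) and MTA fell (−0.89 ± 0.25, adjusted p = 0.0075), lost with quantile or TMM scaling and by edgeR (adjusted p up to 0.17). By limma with BH, 9709 of 19277 genes passed, 1981 up and 7728 down (1284 and 4651 at least 2-fold). The share of passed genes that rose was 20.4%, but 47.0% with quantile scaling, 52.4% with TMM and 50.7% with edgeR on reads, so the excess of falls depended on the scaling. Indole defence had 18 up and 1 down of 19 (19 over the list alone, median 2.65, camera adjusted p = 3.6e-19), PTI response 10 up and 1 down of 14 (11 over the list alone, median 2.06, adjusted p = 1.6e-08) and photosynthesis 0 up and 33 down of 33 (33 over the list alone, median −1.61, adjusted p = 1.1e-08). PTI signalling (5 up, 2 down, 6 over the list alone, median 0.42, adjusted p = 0.00014), jasmonate and ethylene (6 up, 5 down, 11 over the list alone, median 0.33, adjusted p = 0.0016) and salicylic acid (6 up, 3 down, 9 over the list alone, median 0.22, adjusted p = 0.0016) also passed. All were lost with an estimated correlation, at adjusted p = 0.22 or more.

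In mta, flg22 raised uncapped CYP82C2 from 87.7 ± 19.2 to 898 ± 27.6 RPM (n = 3 each, 3.37 ± 0.61, limma adjusted p = 0.0015) and the peroxidase PER4 by 2.66 ± 0.45, and lowered the glucosyltransferase UGT73C1 from 57.8 ± 3.62 to 7.53 ± 1.09 (−2.79 ± 0.27). ALKBH10B rose by 1.06 ± 0.20 and MTA did not pass (−0.61 ± 0.25, adjusted p = 0.091). In total 4211 genes passed by limma with BH, 1163 up and 3048 down (681 and 1599 at least 2-fold). The share that rose was 27.6%, and 54.8% with TMM. The number was 2611, 2327 and 2429 without untreated mta replicates 1, 2 and 3, and 2375, 2282 and 2310 without the treated ones. It was 9524 in a fit of these groups alone. In mta with flg22, indole defence had 12 up and 1 down (16 over the list alone, median 1.21, camera adjusted p = 5.3e-10), PTI response 8 up and 0 down (8 over the list alone, median 1.43, adjusted p = 4.1e-08), photosynthesis 0 up and 15 down (18 over the list alone, median −0.84, adjusted p = 3.9e-05) and cell division 0 up and 5 down (6 over the list alone, median −0.70, adjusted p = 0.0073). PTI signalling (3 up, 1 down), jasmonate and ethylene (3 up, 3 down), salicylic acid (1 up, 0 down), heat and ER chaperones (6 up, 2 down) and the seed list (1 up of 2 tested) also passed, with few members past the threshold. All were lost with an estimated correlation (adjusted p = 0.27 or more). Against Col-0 without treatment, uncapped CYP71A12 was higher in mta, at 658 ± 98.8 RPM (2.71 ± 0.44, limma adjusted p = 0.0023), as was PRX52 (2.75 ± 0.40), and DREB26 was lower (−1.96 ± 0.26). There 669 genes passed, 376 up and 293 down, and 344 and 417 without Col-0 replicates 2 and 3, and 295, 155 and 234 without mta replicates 1, 2 and 3. Leaving out 35SALKBH10B replicate 3 with flg22, which enters only through the shared variance, gave 1870. Indole defence had 7 up and 0 down (11 over the list alone, median 1.202, camera adjusted p = 1.3e-08) and heat and ER chaperones 5 up and 0 down (7 over the list alone, median 0.50, adjusted p = 0.0011). PTI response (2 up), photosynthesis (2 down) and senescence (1 up) also passed, and all were lost with an estimated correlation (adjusted p = 0.58 or more).

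The response of uncapped RNA to flg22 was smaller in mta for a few defence and antenna genes. CYP71A12 had an interaction of −2.95 ± 0.63 (n = 3 per group, limma adjusted p = 0.029) and AT4G28420 of −3.60 ± 0.64, while the antenna gene LHCB2.1 went from 784 to 118 RPM in Col-0 and from 452 to 352 in mta (2.38 ± 0.51). The calls of CYP71A12 and LHCB2.1 were lost in 11 of 20 settings each (adjusted p up to 0.089) and that of AT4G28420 in 3 (up to 0.059). In limma with BH, 303 genes passed, 198 positive and 105 negative. The positive share, 65.35%, was 43.5% with quantile scaling, 29.6% with TMM and 25.6% by edgeR on reads. The number moved from 14 without mta replicate 2 with flg22 to 1571 without 35SALKBH10B replicate 3 with flg22. Indole defence (0 positive, 4 negative, 8 over the list alone, median −1.16, camera adjusted p = 7.2e-14), photosynthesis (6 positive, 0 negative, 13 over the list alone, median 1.00, adjusted p = 1.4e-05) and PTI response (1 positive, 1 negative, 4 over the list alone, median −0.57, adjusted p = 0.010) passed and were lost with an estimated correlation (adjusted p = 0.42 or more).

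Untreated 35SALKBH10B had less uncapped ATCG00790 and IPS1 RNA than Col-0. ATCG00790, a chloroplast gene, fell from 1942 ± 1207 in Col-0 to 64.1 ± 20.7 RPM (n = 3 each, −4.77 ± 0.42, limma adjusted p = 5.1e-06) and IPS1, a non-coding RNA of phosphate starvation, from 33.9 ± 7.68 to 3.34 ± 0.861 (−3.00 ± 0.38). By limma with BH, 2299 genes passed, 566 up and 1733 down (257 and 900 at least 2-fold). The number was 1473, 816 and 1046 without 35SALKBH10B replicates 1, 2 and 3, 1396 without Col-0 replicate 3 and 3909 without 35SALKBH10B replicate 3 with flg22. The share up was 24.6%, and 51.0% with quantile scaling. Heat and ER chaperones (4 up, 0 down, 8 over the list alone, median 0.35, camera adjusted p = 0.0012) and photosynthesis (4 up, 0 down, 4 over the list alone, median 0.17, adjusted p = 0.018) passed upward. PTI signalling (0 up, 4 down, 9 over the list alone, median −0.63, adjusted p = 0.0028), jasmonate and ethylene (0 up, 7 down, 11 over the list alone, median −0.63, adjusted p = 0.018) and NLR receptors (0 up, 4 down, 5 over the list alone, median −0.53, adjusted p = 0.035) passed downward. The guard cell (1 up of 8 tested) and seed lists (1 up of 2 tested) also passed, and none did with an estimated correlation (adjusted p = 0.11 or more).

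With flg22, 1 of the 3 overexpression libraries barely responded. Over the 200 genes that rose most in Col-0, the mean log2(RPM + 1) was 6.18 and 6.02 in 35SALKBH10B replicates 1 and 2 and 4.31 in replicate 3, against 3.83 to 3.98 without treatment. The chloroplast gene ATCG00480 rose from 40.0 ± 9.32 to 2838 ± 173 RPM (6.14 ± 0.22, limma adjusted p = 3.0e-12) and CYP82C2 from 17.5 ± 3.57 to 436 ± 319.6 (4.04 ± 0.61), the latter lost in a fit of these groups alone (adjusted p = 0.12). By limma with BH, 3758 genes passed, 1822 up and 1936 down (1176 and 919 at least 2-fold). Without 35SALKBH10B replicate 3 with flg22 the number was 8175, and without replicates 1 and 2 it was 509 and 578. Without untreated replicates 1, 2 and 3 it was 2300, 1586 and 996, and 25 passed in a fit of these groups alone. Jasmonate and ethylene had 18 up and 0 down of 28 (23 over the list alone, median 1.09, camera adjusted p = 5.9e-12), indole defence 16 up and 1 down (17 over the list alone, median 1.54, adjusted p = 1.1e-10), PTI response 13 up and 0 down (14 over the list alone, median 1.53, adjusted p = 1.1e-10) and PTI signalling 9 up and 0 down (13 over the list alone, median 0.73, adjusted p = 2.0e-06). Salicylic acid (8 up, 0 down, 10 over the list alone, median 0.61, adjusted p = 0.00016), photosynthesis (1 up, 14 down, 19 over the list alone, median −0.73, adjusted p = 3.5e-05) and heat and ER chaperones (0 up, 5 down, 7 over the list alone, median −0.46, adjusted p = 0.0059) also passed, as did NLR receptors (3 up) and guard cell markers (4 down). All were lost with an estimated correlation (adjusted p = 0.22 or more). Without replicate 3 with flg22, indole defence, jasmonate and ethylene, PTI response, salicylic acid, photosynthesis and guard cell markers passed with an estimated correlation too (adjusted p = 0.011 to 0.048).

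The flg22 responses of 35SALKBH10B and Col-0 differed for BIP3, which went from 65.5 to 383 RPM in Col-0 and from 118 to 96.6 in 35SALKBH10B (interaction −2.84 ± 0.32, limma adjusted p = 6.3e-05). ECS1 fell in Col-0 from 229 to 23.4 RPM and stood at 110.5 and 186 in 35SALKBH10B (3.86 ± 0.40). ALKBH10B did not pass (−0.72 ± 0.29, adjusted p = 0.096). The BH threshold in limma was passed by 2809 genes, 2328 positive and 481 negative. The positive share, 82.9%, depended on scaling, with 45.9% by quantile scaling, 39.6% by TMM and 47.0% by edgeR on reads. The number was 910 in a fit of these groups alone, 1537 with quantile scaling, and 1800 and 1690 without untreated 35SALKBH10B replicates 2 and 3. Indole defence (0 positive, 4 negative, 9 over the list alone, median −1.16, camera adjusted p = 8.3e-09), heat and ER chaperones (1 positive, 6 negative, 8 over the list alone, median −0.43, adjusted p = 2.6e-05), photosynthesis (10 positive, 0 negative, 15 over the list alone, median 0.94, adjusted p = 0.00035) and auxin response (4 positive, 0 negative, 5 over the list alone, median 0.75, adjusted p = 0.036) passed, as did the seed list (1 negative of 2 tested), and were lost with an estimated correlation (adjusted p = 0.13 or more). The barely responding replicate 3 with flg22 enters these values. Without it 3550 genes passed, indole defence had a median of −0.58 (1 positive, 5 negative, adjusted p = 0.00054), heat and ER chaperones −0.58 (1 positive, 7 negative, adjusted p = 5.3e-07), photosynthesis 0.68 and auxin response 0.47 (adjusted p = 0.032 each). Jasmonate and ethylene then passed upward (17 positive, 0 negative, median 1.11, adjusted p = 1.7e-07), and no list passed with an estimated correlation (adjusted p = 0.076 or more).

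**Figure D2:**
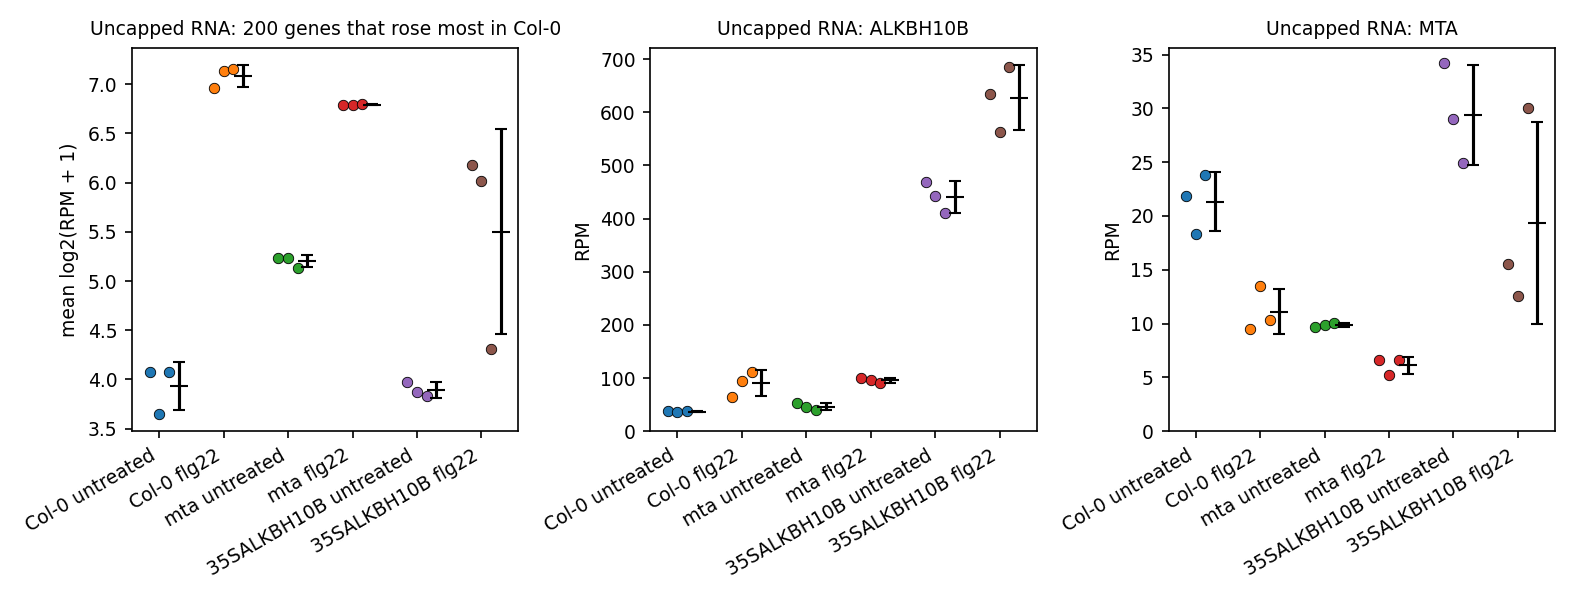
Uncapped RNA in each GMUCT library (dots) with group mean ± SD, n = 3 per group: mean log2(RPM + 1) of the 200 genes that rose most with flg22 in Col-0, and RPM of ALKBH10B and MTA. Replicate 3 of 35SALKBH10B with flg22 lies near the untreated libraries in the left panel and keeps high ALKBH10B.

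Few genes passed for a change in uncapped RNA beyond their mRNA, and their number moved with single libraries. In Col-0 with flg22, TOC159, a receptor of the chloroplast import machinery, went from 391 ± 118 to 122 ± 16.3 RPM, a change of −2.94 ± 0.34 relative to mRNA (n = 3 per group and kind, limma adjusted p = 8.4e-06), and RPA1A, a replication protein, changed by 2.56 ± 0.25 (adjusted p = 3.4e-07). In mta with flg22, DCP1 changed by 1.41 ± 0.25 (adjusted p = 0.026) and the glutamate decarboxylase GAD2 by −1.33 ± 0.23 (adjusted p = 0.026). Between untreated mta and Col-0, BIG, an auxin transport protein, changed by −1.14 ± 0.22 (adjusted p = 0.03). The calls of DCP1 and GAD2 were lost in 14 of 18 settings each (adjusted p up to 0.14 and 0.12) and that of BIG in 10 (up to 0.16). ALKBH10B did not pass in any (−0.09 ± 0.22, 0.88 ± 0.22 and −0.62 ± 0.22). By limma with BH, 75 of 17596 genes passed in Col-0 (25 up, 50 down; 1399 at unadjusted p under 0.05), 9 in mta (5 up, 4 down; 1298 unadjusted) and 15 between mta and Col-0 (4 up, 11 down; 1835 unadjusted). With a pseudocount of 5 these were 276, 76 and 79. As each library was left out, they ranged from 54 to 148, 1 to 29 and 0 to 25. No list passed for flg22 (adjusted p = 0.98 and 0.79 or more with an estimated correlation). NLR receptors passed between mta and Col-0 (0 up, 0 down of 14, 2 over the list alone, median −0.50, camera adjusted p = 0.0028), lost at adjusted p = 0.58 or more with an estimated correlation.

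Peaks of m6A sat less often near gene ends in every mta seedling library than in any Col-0 library of the same treatment. In untreated Col-0, 47.4 ± 0.818% of summits in genes lay in the last 20% of the gene span (mean ± SD, n = 2), against 36.7 ± 1.22% in untreated mta (n = 3), a difference of −10.7 points. With flg22 the share was 41.3 ± 1.12% in Col-0 (−6.12) and 33.5 ± 1.23% in mta (−3.24), n = 3 each. All 3 differences had the smallest exact permutation p the design allows, 0.1, two-sided (adjusted p = 0.23), so 0.05 could not be reached. Untreated mta libraries held fewer summits in the last 20% than Col-0 ones (6786 to 6901 against 7398 and 8193) and more elsewhere in genes (11173 to 12365 against 8406 and 8887). In 35SALKBH10B the share was 45.1 ± 2.04% untreated (−2.28 against Col-0; exact p = 0.3, adjusted 0.53) and 44.0 ± 0.450% with flg22 (−1.11; exact p = 0.6, adjusted 0.70). In leaves, 28.0 ± 5.02% of Col-0 summits at 00, 29.0 ± 6.29% at 24 and 26.9 ± 5.14% in mta at 00 lay there (exact p = 0.8 and 0.6).

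**Figure D3:**
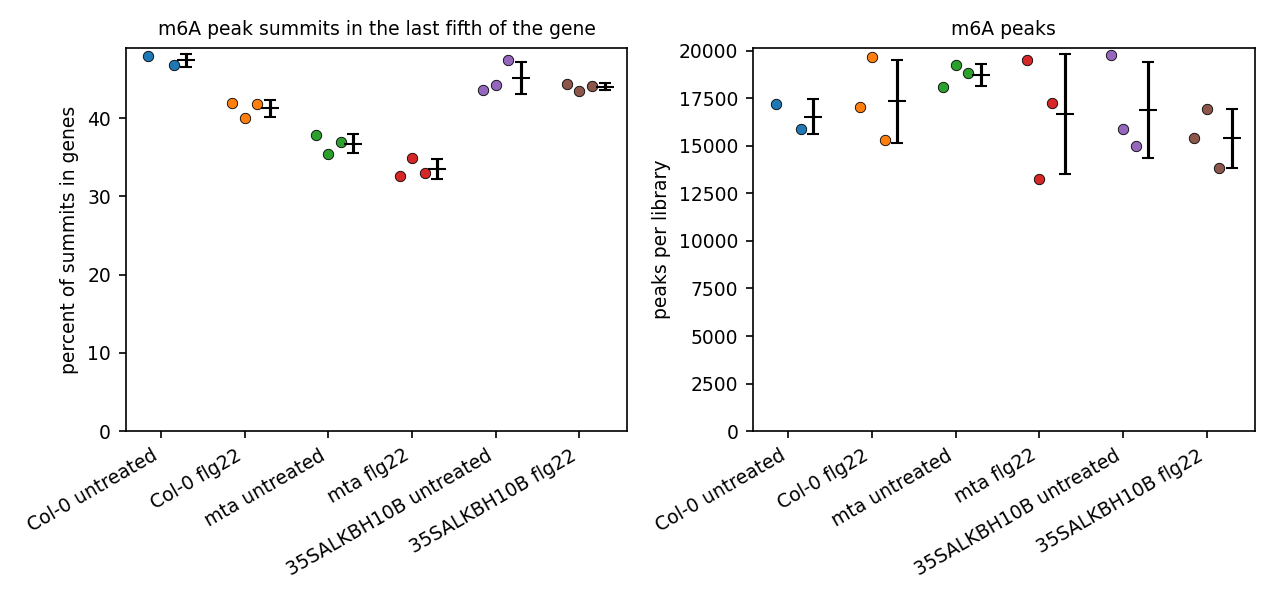
Percent of m6A peak summits in genes that lie in the last 20% of the gene span (left) and m6A peaks per library (right) in seedlings; dots are libraries, bars mean ± SD, n = 2 for untreated Col-0 and 3 otherwise. The share near gene ends is lower in mta, and untreated mta libraries have more peaks than untreated Col-0 ones.

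An unpaired exact test, which cannot reach 0.05 here, showed no group difference in m6A peak numbers. Untreated Col-0 had 16539 ± 919 peaks (n = 2), Col-0 with flg22 17330 ± 2186, untreated mta 18722 ± 591, mta with flg22 16664 ± 3160, untreated 35SALKBH10B 16873 ± 2527 and 35SALKBH10B with flg22 15385 ± 1544 (n = 3 each). Leaves had 24099 ± 5095 in Col-0 at 00, 24602 ± 3769 at 24 and 21120 ± 5411 in mta at 00 (n = 3 each). Exact two-sided permutation gave adjusted p of 0.7 for untreated mta against Col-0 (unadjusted 0.1, the smallest possible) and 1 for the other 6 comparisons. Covered length was 4.37 ± 0.389 Mb in untreated Col-0 and 4.999 ± 0.253 Mb in untreated mta, and did not pass in any of 7 comparisons (adjusted p = 0.7 to 1). Genes with a peak were 10932 ± 752 and 11085 ± 234 in these groups. With flg22 they were 9414 ± 1168 in mta, below every untreated mta library (8152 to 10458 against 10929 to 11354; exact p = 0.1, the smallest possible), and adjusted p was 0.7 to 0.9 over the comparisons.

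Several genes with a peak only under flg22 in Col-0 had more RNA there. PER4 had a peak in every Col-0 library with flg22 and none without, at 1679 and 85.8 CPM. So did PRX52 (802 and 22.4 CPM), AT4G32020 (516 and 502) and RPA1A (249 and 826). In the reverse pattern, CARB stood at 777 CPM with flg22 and 3753 without, and AT5G03350 at 18.6 and 174. In Col-0, 372 genes had a peak in every library with flg22 and none without, and 711 the reverse, of which 191 and 129 had 10 CPM or more in both groups. In mta these were 92 and 696 (50 and 272 at 10 CPM), and in 35SALKBH10B 330 and 340. VAB2 was marked in mta only with flg22, at 144 and 157 CPM. Without treatment, 335 genes were marked only in mta and 261 only in Col-0 (179 and 168 at 10 CPM). For 35SALKBH10B against Col-0 these were 68 and 198. ROC5 (541 and 621 CPM) and PER4 (300 and 85.8) were marked only in mta and RAP2.4 (179 and 237 CPM) only in Col-0. In Col-0 leaves 291 genes were marked only at 24 and 164 only at 00 (162 and 45 at 10 CPM). At 00, 37 were marked only in mta and 296 only in Col-0 (25 and 148 at 10 CPM). Untreated seedling Col-0 had 2 lists, an easier rule, and genes with a peak differed between libraries. Larger counts one way thus show no gain or loss of marking.

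Changes in mRNA of genes with m6A peaks depended on how these were chosen, and every choice was made in Col-0. With genes that had a peak in every untreated Col-0 library, the median log2(CPM + 1) of 9569 such genes in Col-0 seedlings stood 0.24 ± 0.02 above that of 8663 expression-matched genes without a peak, and −0.19 ± 0.04 with flg22 (mean ± SD, n = 3 each), a change of −0.43. With genes chosen in the Col-0 libraries with flg22 the change was 0.16, and −0.07 with genes marked in both groups (exact p = 0.1 and 0.3). In mta the change was −0.24, and 0.12 and −0.02 in the same order (exact p = 0.1 each). Between untreated mta and Col-0 it was −0.15, and −0.01 and −0.03 (exact p = 0.9 and 0.2). In Col-0 leaves the difference went from 0.06 at 00 to 0.30 at 24 (0.24), over 6674 genes with a peak and 7865 without, but changed by −0.38 with genes chosen at 24 and −0.11 with genes marked at both times (exact p = 0.1 each). In mta leaves these were 0.04 (exact p = 0.5, adjusted 0.5), −0.33 and −0.18 (exact p = 0.1 each). Between mta and Col-0 leaves at 00 they were −0.17, −0.29 and −0.28, lower each time (exact p = 0.1 each), although all genes were chosen in Col-0. With genes chosen in untreated Col-0, each change but that in mta leaves had exact permutation p = 0.1, two-sided, the smallest with 3 against 3 libraries (adjusted p = 0.12). For uncapped RNA relative to the mean mRNA of the group, over 9544 and 7669 genes, the difference was 0.73 untreated and 0.70 with flg22 in Col-0 (−0.03; exact p = 0.7, adjusted 0.7), and the change was 0.13 and 0.04 with the other choices (exact p = 0.2 and 0.7). It changed by −0.17 in mta with flg22 (−0.08 and −0.09 with the other choices, exact p = 0.1 each), and was 0.09 higher in untreated mta than in Col-0 (0.03 and 0.02, exact p = 0.6 and 0.9), with exact p = 0.1 and adjusted p = 0.15 each for genes chosen in untreated Col-0.

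**Figure D4:**
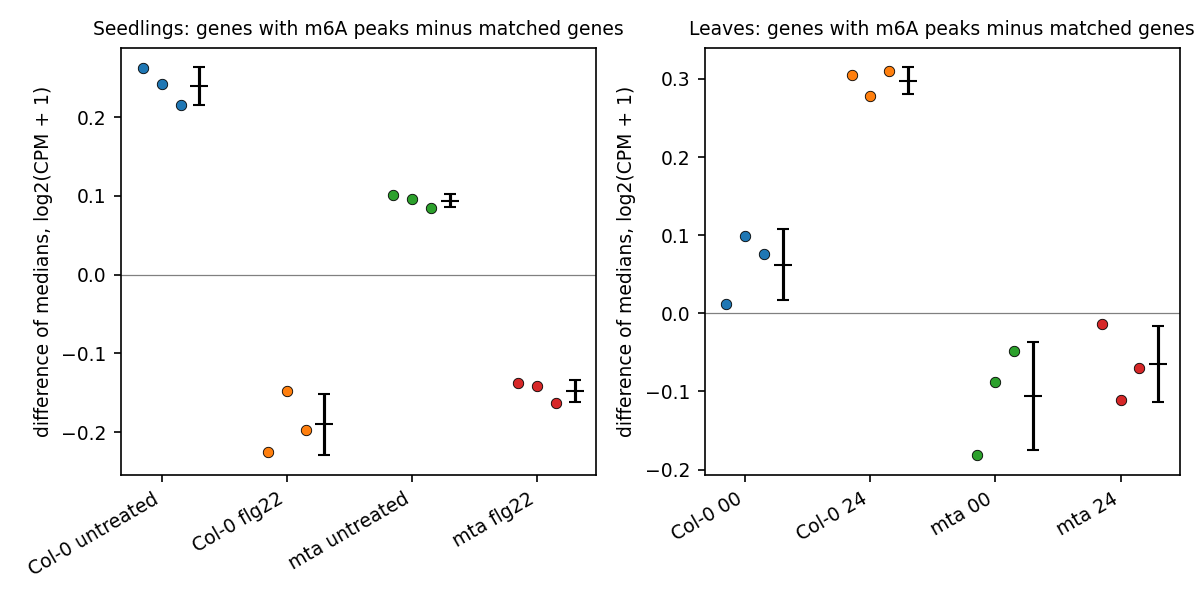
Difference in median log2(CPM + 1) between genes with m6A peaks in every untreated (left) or 00 (right) Col-0 library and expression-matched genes without, per mRNA library (dots) with group mean ± SD, n = 3 per group, in seedlings (left) and leaves (right). Values fall with flg22 in seedlings and rise from 00 to 24 in Col-0 leaves, and both directions turned with genes chosen in the other Col-0 group.

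Genes that flg22 raised most were higher in mta without treatment. Of the 200 that rose most with flg22 in uncapped RNA of 35SALKBH10B, 182 were tested in seedling mRNA, where 145 rose and 5 fell in untreated mta against Col-0 (median 1.29, camera adjusted p = 6.1e-107, estimated 7.6e-06). Of the 200 that rose most by 24 in Col-0 leaves, 163 were tested in seedlings, where flg22 raised 93 and lowered 29 in Col-0 (median 1.01, camera adjusted p = 4.7e-21, estimated 2.5e-05). In untreated mta against Col-0, 94 of them rose and 10 fell (median 0.87, camera adjusted p = 9.4e-41, estimated 2.9e-06). Their flg22 response was smaller in mta, with 23 positive and 69 negative interactions (median −0.52, camera adjusted p = 2.1e-18, estimated 2.1e-05). Of the 200 that rose most with flg22 in Col-0 seedlings, 99 were tested in leaves, where 81 rose and 4 fell by 24 in Col-0 (median 4.89, camera adjusted p = 2.4e-09), lost at adjusted p = 0.23 with an estimated correlation.

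Under flg22, mta was no longer above Col-0 for early defence genes. In mta against Col-0 with flg22, indole defence had 1 up and 14 down of 18 (median −0.38, camera adjusted p = 1.5e-09, estimated 0.0096), PTI signalling 2 up and 9 down of 17 (median −0.32, adjusted p = 0.0015, estimated 0.043) and PTI response 3 up and 7 down of 14 (median −0.33, adjusted p = 0.0089, estimated 0.043). Heat and ER chaperones were higher, with 10 up and 3 down of 18 (median 1.21, adjusted p = 9.7e-21, estimated 0.0067), as was senescence, with 4 up and 0 down of 7 (median 0.75, adjusted p = 4.8e-05, estimated 0.010). Jasmonate and ethylene had 1 up and 15 down of 28 (median −0.22, adjusted p = 0.0042), lost at adjusted p = 0.17 with an estimated correlation.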

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

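The tests of the share of summits near gene ends, of the odd GMUCT library, of GMUCT between genotypes and of the level under flg22 of genes chosen in 35SALKBH10B were chosen after the result was seen, while the tests of the peak-carrying genes, of single libraries, of scaling and of the final level for genes chosen from leaves were written before they were run.

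The mta and Col-0 seedlings differed in their flg22 response for 3803 genes, and the mta and Col-0 leaves differed in their response from 00 to 24 for 1834. The 35SALKBH10B and Col-0 seedlings differed in the uncapped response for 2809 genes, and mta and Col-0 for 303. These are given because an effect seen in one line was tested for a difference in the other. Features named NPC, outside the gene loci, held at least 26.06% of seedling mRNA counts, and these features were not analysed here.

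Fewer m6A summits near gene ends in untreated mta than in Col-0 could come from different genes being called, from different peak numbers, or from fewer marked sites. Among genes with a peak in every library of both groups, the share still fell by 7.64 points (−10.7 points over all genes). Different genes thus do not explain all of it. With equal numbers of top peaks the share fell by 11.8 points, so the number of called peaks does not explain it. Summits near gene ends were fewer, by 497 between the highest mta and the lowest Col-0 library (−497), and summits elsewhere were more (11173 to 12365 against 8406 and 8887). Whether marked sites were lost, or more sites were called elsewhere for a technical reason, stays open, as only 2 untreated Col-0 peak lists were used here and the depth of the m6A libraries is unknown.

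Replicate 3 of 35SALKBH10B with flg22 lay with the untreated GMUCT libraries. A swap with an untreated library of the line is excluded, since the highest flg22 response share among these was 0.0389, and 0.188 in replicate 3 itself. Another genotype is excluded, because its ALKBH10B RPM was higher than the highest library of the other lines by 573, and so is low depth, as it held 16.2 × 10⁶ reads. A sample that was not treated or did not respond fits the response share of 0.188, and its high share of reads outside nuclear gene loci (1.60%, against 0.303 to 0.387% untreated) is like that of the other treated libraries of the line, although this share did not rise with flg22 in Col-0 or mta. Which of these occurred stays open.

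Genes that rise with flg22 were higher in untreated mta than in untreated Col-0. Chance values of shared untreated libraries are excluded, because genes chosen in 35SALKBH10B alone gave a median of 1.29. A single library is excluded at a lowest median of 1.19 when any library was left out, and scaling at 1.28 with library size alone. Under flg22 the median was 0.353 for genes chosen from leaves (60 higher, 34 lower of 163). For those chosen in 35SALKBH10B it was −0.434 (22 higher, 106 lower of 182). Both lay beyond 0.2, but opposite signs leave a like final level open. A higher resting level in mta goes with these values, while the end level differs by gene set.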

How the results depend on the processing

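Of 989 results for named genes, 984 kept their direction in every setting and 696 of these lost no call, while 288 lost a call in at least 1 setting. Those named in the results have it beside them. Settings that moved a count of a comparison by more than 1.5-fold or turned a direction follow, with the cause not tested unless stated. A replicate block was tried throughout, since some leaf groups shared structure by number. With equal numbers of top peaks the number per library is fixed by construction and gives no value. Alternatives chosen at the start for mRNA of 35SALKBH10B, for the 3′ untranslated share and for an independent set were not run, because these results are not analysed here.

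With every annotated feature tested, 18662 passed for flg22 in Col-0, 12990 in mta and 9964 for untreated mta against Col-0, since mirrored features enter by construction. With a fold of 2 or more required, the counts were by construction lower: 5326 for flg22 in Col-0 seedlings, 2080 in mta, 1092 for untreated mta against Col-0, 1284 for the interaction, 7305 for leaves from 00 to 24 in Col-0, 5486 in mta, 1821 for mta against Col-0 at 00 and 1107 for the leaf interaction. The leaf interaction was 2970 by DESeq2, 2900 with a replicate block and 3194 with replicates 2 and 3 alone. Lists that passed by fry, which tests a list against 0 and not against other genes, were 15 for flg22 in Col-0, 16 in mta, 13 for untreated mta against Col-0, 12 for the interaction and 13 for Col-0 leaves. With an estimated correlation they were 3 for untreated mta against Col-0 and 0, 0, 0 and 0 for the 4 leaf comparisons. With a replicate block 6 lists passed in place of 5 for mta against Col-0 leaves at 00.

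For GMUCT, a fit of the compared groups alone gave 9524 for flg22 in mta, 25 in 35SALKBH10B, 910 for the 35SALKBH10B interaction and 1557 for the mta interaction. Quantile scaling gave 1537 for the 35SALKBH10B interaction, and its lists without replicate 3 with flg22 are given above. A pseudocount of 5 gave 1015 for untreated mta against Col-0 and 589 for the mta interaction, which was 155 with a pseudocount of 0.1, 190 with a replicate block and 540 by edgeR on reads. For uncapped relative to mRNA, a pseudocount of 5 gave 276 in Col-0, 76 in mta and 79 for mta against Col-0, a pseudocount of 0.1 gave 5 and 5 for the last pair, a filter of 5 gave 40 in Col-0, a block within library kind gave 2 in mta and 6 for mta against Col-0, and TMM for both kinds gave 3 and 8.

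For m6A, keeping peaks with −log10 q of 5 or more changed the difference in peak number to −589.8 (flg22 in Col-0), −181.5 (35SALKBH10B against Col-0) and −921.7 (Col-0 leaves), in covered Mb to −0.1414 (flg22 in Col-0) and −0.2642 (Col-0 leaves), in genes with a peak to −110.5 (mta against Col-0) and −332.7 (Col-0 leaves), and the genes marked in one group only to 227 (Col-0 leaves) and 158 (mta against Col-0 leaves). Equal numbers of top peaks gave 112 more genes with a peak for flg22 in 35SALKBH10B, −461.3 for mta against Col-0, and 438 genes marked in one group only for 35SALKBH10B against Col-0. A replicate block gave −1104 peaks for 35SALKBH10B against Col-0. At 10 CPM or more in both groups, genes marked in one group only were 320 (flg22 in Col-0), 322 (flg22 in mta), 347 (mta against Col-0), 207 (Col-0 leaves) and 173 (mta against Col-0 leaves). With a peak in any library the score of m6A genes in mta leaves changed by −0.007227. With m6A genes chosen in the Col-0 libraries with flg22 or at 24, the score turned to 0.156 (flg22 in Col-0), 0.1163 (flg22 in mta), −0.384 (Col-0 leaves), −0.3288 (mta leaves) and, for uncapped relative to mRNA, 0.1332 (flg22 in Col-0). With genes marked in both Col-0 groups it turned to −0.1071 (Col-0 leaves), −0.1837 (mta leaves) and 0.04216 (uncapped, flg22 in Col-0).

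Leaving out each library in turn gave these lowest and highest values. For mRNA they were 3574 and 4816 for mta against Col-0 leaves at 00, and 809 and 2170 for the leaf interaction. For GMUCT they were 2282 and 6081 for flg22 in mta, 509 and 8175 in 35SALKBH10B, 155 and 1870 for untreated mta against Col-0, 816 and 3909 for 35SALKBH10B against Col-0, 1690 and 3553 for the 35SALKBH10B interaction and 14 and 1571 for the mta interaction. Highest values there arose without 35SALKBH10B replicate 3 with flg22, apart from 3553, which arose without replicate 2. For uncapped relative to mRNA they were 54 and 148 in Col-0, 1 and 29 in mta and 0 and 25 for mta against Col-0.

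For m6A, the difference in peak number ranged from −367.5 to 1804 (flg22 in Col-0), −1104 to 1265 (35SALKBH10B against Col-0) and −1903 to 3172 (Col-0 leaves). Covered Mb ranged from −0.1851 to 0.6754, −0.561 to 0.2535 and −0.03274 to 0.7025 in the same order. Genes with a peak ranged from −710.2 to 395.3 (flg22 in 35SALKBH10B), −379 to 685 (mta against Col-0) and −120.5 to 845 (Col-0 leaves). The share near gene ends ranged from −1.86 to 0.05199 points (flg22 in 35SALKBH10B), −2.337 to 3.903 (Col-0 leaves) and −3.931 to 1.829 (mta against Col-0 leaves). The uncapped score of m6A genes for flg22 in Col-0 ranged from −0.09681 to 0.01367. With the smallest p of 0.1, none of these differences could pass 0.05.

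Other directions turned as follows, on results that did not pass apart from 1 set of genes. By fry, RNA decay for flg22 in mta had adjusted p = 0.7856, guard cell markers for untreated mta against Col-0 0.7314, and auxin response, root markers and seed markers in mta leaves 0.6284, 0.3429 and 0.8534, with root markers at 0.9806 under a block. That set, the 200 genes that fell most with flg22 in Col-0 seedlings, passed downward in mta leaves (median −0.6501, camera adjusted p = 0.0147), lost at 0.2267 with an estimated correlation. With 50 genes the median was −0.2887 and the camera test turned upward (adjusted p = 0.9902). The ALKBH10B interaction ranged from −0.05369 to 0.2136 in leaves as each library was left out, and for GMUCT in mta from −0.3895 to 0.002476, above 0 only without Col-0 replicate 3 with flg22. The MTA interaction of 35SALKBH10B ranged from −0.1203, without replicate 3 with flg22, to 0.478. It was −0.2144 with quantile scaling, −0.1234 by edgeR and −0.2072 with TMM, and that of mta was −0.007366, −0.06313 and −0.019. ALKBH10B relative to mRNA in Col-0 ranged from −0.2627 to 0.1293, above 0 only without replicate 1 with flg22, and was 0.04781 with TMM.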

Other observations

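Untreated mta seedlings held both defence and heat genes high, and flg22 separated them. HSP101 and HSP90.1 were raised without treatment, and under flg22 heat and ER chaperones stayed above Col-0 (median 1.21, 10 of 18 up), while indole-defence genes ended lower (median −0.38). Genes that flg22 raised in 35SALKBH10B were high in untreated mta (median 1.29). This suggests that mta seedlings may rest in a partly induced state, from which the further response is smaller. Genes that flg22 raises could also be short-lived RNAs that m6A normally destabilises, or the line could be stressed from its long-term low MTA. A time course of CYP71A12 and HSP101 RNA after transcription is stopped, in untreated mta and Col-0, would separate slower decay from higher synthesis.

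ALKBH10B RNA itself rose with flg22 in Col-0 seedlings, and with it the share of summits near gene ends was lower (−6.12 points). In mta, where this share was already low, ALKBH10B stood higher before treatment. Within genes marked in every library the share differed by −7.64 points in mta, a check not made for flg22. In mta more summits elsewhere in genes add to the lower share. In untreated 35SALKBH10B the share was 45.1% and changed by −1.11 points with flg22 (exact p = 0.6). Whether ALKBH10B sets the share stays open, as it was measured there only as uncapped RNA. Single-site m6A of marked genes such as RAP2.4, with known input depth, would test it.

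Genes with m6A peaks in every untreated Col-0 library stood lower against matched genes with flg22 in Col-0 seedlings (−0.43), yet higher (0.16) when they were chosen in the flg22 libraries. In leaves the turn was from 0.24 to −0.38. If peaks are called more easily at high RNA levels, genes chosen in one group could stand higher in that group by this choice alone. Genes marked in both groups changed by −0.07 and −0.11. Uncapped RNA of marked genes relative to mRNA was high (0.73 above matched genes), and its change with flg22 in Col-0 was −0.03, 0.13 and 0.04 for the 3 ways of choosing genes, so faster decapping stays open.

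ATCG00480, a chloroplast RNA, rose with flg22 in uncapped RNA of 35SALKBH10B in all libraries, including replicate 3, which had a response share of 0.188 for nuclear flg22 genes. This could mean that the library was treated and responded weakly, or that chloroplast content differed by handling. Reads outside nuclear gene loci rose with flg22 only in this line (1.23 to 1.75% against 0.303 to 0.387%), and not in Col-0 (0.506 to 0.526% against 0.527 to 0.955%) or mta (0.519 to 0.569% against 0.592 to 0.680%), so the rise need not mark the treatment. Its ALKBH10B RPM, higher by 573 than the other lines, places it in 35SALKBH10B.

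Regrouping libraries at random tested whether the groups stand out. For 3 against 3 libraries, only 10 splits exist, too few for a share under 0.05. The real split was the top 1 of 10 in every such mRNA and GMUCT comparison, with a highest other count of 0 in all mRNA comparisons, in flg22 of Col-0 and mta and in untreated mta against Col-0, 3 for flg22 in 35SALKBH10B (real 3758) and 2 for 35SALKBH10B against Col-0 (real 2299). Counts of splits include the real one. For the interactions, 1 of 30 splits reached the real count in seedlings (3803, highest other 2963) and 1 of 30 in leaves (1834, highest other 1101). For GMUCT, 2 of 100 did so for 35SALKBH10B (2809, highest other 2986) and 2 of 100 for mta (303, highest other 787). For uncapped relative to mRNA, 12 of 100 reached 75 in Col-0 (highest other 8619), 10 of 100 reached 9 in mta (highest other 8262) and 11 of 100 reached 15 for mta against Col-0 (highest other 3913). Splits that call many times the real count point to a structure of the samples, since reversing the groups in 1 kind of library adds the effects. They are thus no measure of chance for these few genes beyond mRNA.

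For genes marked in every library of one group only, the real split was the top 1 of 10 for flg22 in Col-0 (1083, highest other 336), in mta (788, highest other 80) and in 35SALKBH10B (670, highest other 154), for untreated mta against Col-0 (596, highest other 231), for Col-0 leaves (455, highest other 170) and for mta against Col-0 leaves (333, highest other 320). It was among 3 of 10 for 35SALKBH10B against Col-0 (266, highest other 415), so no marking difference is shown there. The 10 splits are too few for a share under 0.05.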
